A study of Triticum aestivum with 6 samples.

How the data were processed

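Leaf RNA of bread wheat (Triticum aestivum), a hexaploid with A, B and D subgenomes, was sequenced from plants grown at 23 °C or at 4 °C, with 3 libraries per condition. Per the labels' protocols, the plants stood in separate chambers with a 16-hour photoperiod, total RNA was extracted with a Qiagen plant RNA kit, and libraries were made with Illumina TruSeq reagents. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.30, STAR 2.3.0e, Cufflinks 2.1.1 and Cuffdiff 2.1.1 were used. Their roles and settings, the genome build and the annotation are not given in the sources used here.

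The authors deposited FPKM values (fragment numbers scaled by transcript length and by the number of mapped fragments) of 442311 assembled transcripts, with 1 value per transcript and condition. Per the file headers, the columns are control and cold. They were taken as the 23 °C and the 4 °C condition, because 4 °C is the lower of the 2 temperatures in the labels. No column belongs to a single library, so how the 3 libraries of a condition were combined is not given in the sources used here, and no spread between replicates could be computed. The authors' values are therefore printed with no SD, no n and no p-value. Transcript numbers run to 442391, and 80 of them are absent from the table used here.

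Read counts and library depths were not used here. Low values were inspected for steps of 1 read. Among 6367 genes with 1 transcript and a mean above 0 and under 0.5 FPKM, the most frequent ratio of the conditions, at 4 decimals, was shared by 5 genes, so no step was found and the depth is unknown. No confidence interval of a gene's level and no detection limit can be given. The FPKM columns summed to 1006040 at 23 °C and 1052450 at 4 °C.

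The table pairs 384429 transcripts with 99386 gene IDs, each of which carries its chromosome arm, and lists 57882 transcripts with no gene ID. Chromosome 3B is not split into arms, which leaves 41 arms. IDs were looked up in a table of RefSeq genes of the Chinese Spring assembly IWGSC CS RefSeq v2.1, and 0 of the 99386 IDs matched. Genes therefore have no names, functions or coordinates here. The 24 gene lists fixed before the data were examined (lipid pathways, cold-regulated genes, photosynthesis, tissue markers and others) could not be applied and gave no result.

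A gene's FPKM was the sum over its transcripts. Genes with a mean over both conditions of at least 1 FPKM were compared, as the log2 of (FPKM at 4 °C + 1) minus the log2 of (FPKM at 23 °C + 1). The pseudocount of 1 understates the change of low genes. The tests planned before the data were examined (limma on the libraries, gene set tests, and exact permutation tests of subgenome shares) need values per library and were not made. In their place, genes that differed by at least 2-fold on this scale were counted as a description of these 2 columns. For each arm, the median change was placed among those of 10000 random lists of as many genes, drawn with replacement and matched on mean FPKM in 20 bins. Such a percentile describes these columns; genes are not replicates. The level of a chromosome was described by the 90th percentile of FPKM over all its gene IDs, divided by the median of that value over chromosomes 1 to 5 and 7 of the same subgenome. The transcript with the most FPKM was compared between conditions in genes with several transcripts and at least 5 FPKM in both.

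The counting step was tested on simulated data in the comparison of 4 °C with 23 °C, over 42972 genes of which 200 were given a known change at 4 °C, 100 up and 100 down from the same 23 °C levels. At 2.5-fold it recovered 79 of those raised and 42 of those lowered, at 4-fold 100 and 67, and at 8-fold 100 and 96. With a pseudocount of 0.1 in place of 1 it recovered 100 and 100 at each fold, so the pseudocount of 1 accounts for the loss, which was larger among lowered genes in this simulation. The simulated columns were otherwise equal and held no noise, so false calls were not tested. The filter was not applied again after the change, unlike in the data, so the larger loss among lowered genes need not carry over to them. In 5 simulations of the arm step, each over 42972 genes, the arm shifted by 0.25 on the log2 scale was found in 5, and 12 of 200 unshifted arms lay outside the central 95% of random lists. Smaller shifts, such as that of 4AS (median 0.17, central 95% of random lists 0.04 to 0.15), were not simulated. Changes were shuffled over genes of like mean FPKM, which removed any dependence within an arm. Both results therefore hold for independent genes alone.

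The rule for named genes, fixed before the data were examined, gives for genes without names the 2 IDs with the largest rise and the 2 with the largest fall among those with a mean of at least 5 FPKM. Its conditions on adjusted p and on single libraries could not be applied. Alternatives planned in advance were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, and the subgenome shares without low or without the 100 most abundant features. Leaving out libraries, a replicate block and other variance settings needed values per library and were not run. The 90th percentile measure, the dominant transcripts and the choice of the arms and sets described in detail were made after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.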

Results

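Transcript levels were measured in wheat leaves by RNA sequencing under 2 growth temperatures, 23 °C and 4 °C, with 3 libraries each. The labels give 2 weeks for the 23 °C plants and 4 weeks for the 4 °C plants, and speak of 2 weeks of cold. The labelled weeks, the growth chamber and the temperature change together, so every difference below is one between plants that differed in all of these. The table holds the authors' single value per condition, so no difference has a replicate check, and how large a difference the spread between libraries alone would give is unknown. Of 99386 genes, 41820 reached 1 FPKM at 23 °C and 41997 at 4 °C. A further 27163 genes were listed at 0 in both.

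The comparison of 4 °C with 23 °C asked which leaf transcripts differed in level between the growth temperatures. More genes were higher in the cold than lower. Among 42972 genes with a mean of at least 1 FPKM, 5318 were at least 2-fold higher at 4 °C and 2846 at least 2-fold lower, on the log2(FPKM + 1) scale. At a threshold of 4-fold, 1406 genes were higher and 591 lower, and at 8-fold 485 were higher and 158 lower. The median log2 change over all genes was 0.09, with quartiles of -0.34 and 0.54.

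Part of this excess depended on how the columns were scaled. Median-of-ratios scaling lowered FPKM at 4 °C relative to 23 °C by 0.11 in log2 of FPKM. On the log2(FPKM + 1) scale the median change went from 0.09 to 0.0006, with 4667 genes at least 2-fold higher and 3363 at least 2-fold lower. Higher genes made up 65.1% of those that differed 2-fold in the deposited values, 58.1% after median-of-ratios scaling and 52.0% after quantile normalization, which forces the distributions of the 2 columns to be equal. At 8-fold these shares were 75.4%, 71.1% and 64.0%. With a pseudocount of 0.1 in place of 1 and the deposited values, the share at 2-fold was 60.9%.

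The genes with the largest differences were on in one condition and near or at 0 in the other. Traes_5DL_8BBB72707, on the long arm of chromosome 5D, was listed at 0 at 23 °C for both of its transcripts, and at 9748 FPKM at 4 °C it was the most abundant of all genes. Traes_2BL_6382E3EFF, on the long arm of 2B, had 0.824 FPKM at 23 °C and 2112 FPKM at 4 °C, a ratio of 2563, and ranked 26 among all genes at 4 °C. In the other direction, Traes_7AL_9EFCAA261 had 126.6 FPKM at 23 °C and Traes_7BS_1A4F10567 had 99.5 FPKM, and both were listed at 0 at 4 °C. A value of exactly 0 in such a table can be a failed estimate, so no fold is given for these 3 genes. The table pairs none of the 4 with a function.

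More genes were under 1 FPKM at 23 °C and at least 100 FPKM at 4 °C than the reverse. There were 32 such genes at 4 °C, with a median of 259.6 FPKM, and 1 gene, Traes_7AL_9EFCAA261, with at least 100 FPKM at 23 °C and under 1 FPKM at 4 °C. In all, 1223 genes had at least 100 FPKM at 4 °C and 906 at 23 °C. Among transcripts with no gene ID the same counts were 17 and 5. The contrast was less steep at a lower cut. Of 12533 genes with at least 10 FPKM at 4 °C, 41 were listed at 0 at 23 °C. A further 30 were above 0 and under 0.1 FPKM, and 180 from 0.1 to under 1 FPKM. Of 10862 genes with at least 10 FPKM at 23 °C, these counts at 4 °C were 25, 2 and 56. Traes_7BS_1A4F10567, at 99.5 FPKM at 23 °C, lay just below the cut of 100 FPKM. The counts were not repeated after scaling. Of the 32 genes, 31 had a value above 0 at 23 °C. They lay on 12 chromosomes. The arm 7DS held 7 of them, 7AS held 5, 5BL and 5DL held 4 each, and 4AL held 3. By subgenome, 10 were on A, 8 on B and 14 on D chromosomes.

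In the deposited values, direction varied with abundance. This was counted with a pseudocount of 1 alone, which understates the change of low genes, and was not repeated after scaling. Of the 5144 genes with a mean of 20 to under 100 FPKM, 23.2% were at least 2-fold higher at 4 °C and 7.78% at least 2-fold lower, and the median log2 change was 0.35. Of the 22110 genes with a mean of 1 to under 5 FPKM, 8.31% were higher and 5.94% lower, with a median of 0.01. The 88 genes with a mean of at least 1000 FPKM went the other way. Only 6 of these were at least 2-fold higher at 4 °C and 19 were at least 2-fold lower, with a median of -0.28.

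**Figure D1:**
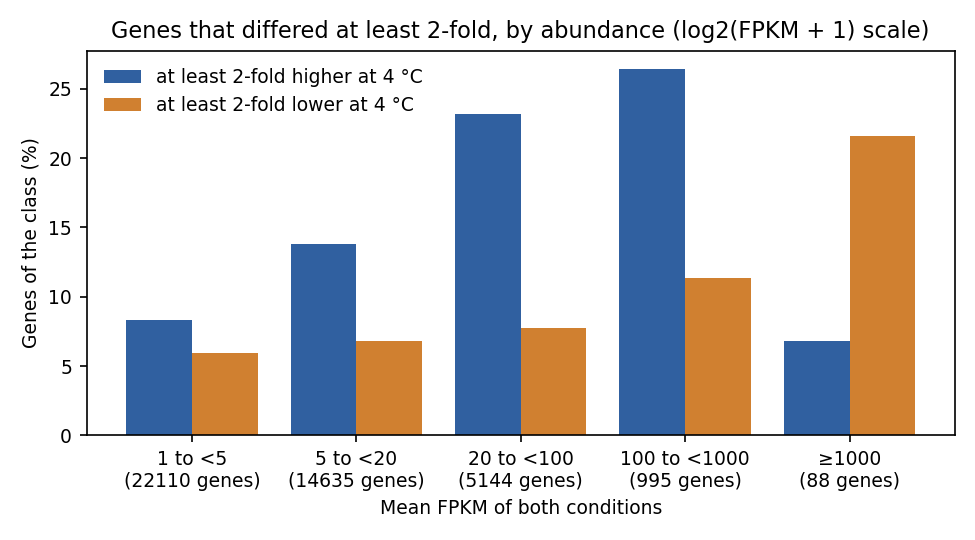
The bars show the percentage of genes at least 2-fold higher (blue) or lower (orange) at 4 °C, for classes of mean FPKM along the horizontal axis with the number of genes in each. Higher genes outnumber lower ones in each class up to 1000 FPKM, and lower genes (21.6%) outnumber higher ones (6.82%) among the 88 genes at or above 1000 FPKM.

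The 100 most abundant genes took 22.5% of all FPKM at 23 °C and 18.0% at 4 °C. Of these genes, 70 were lower at 4 °C and 30 higher. The short arms of homoeologous group 2 (2AS, 2BS and 2DS) held 23 of them, of which 20 were lower at 4 °C and 12 were at 50% or less of their 23 °C value. Together these 23 genes went from 5.92% to 2.68% of all FPKM. The long arms of group 5 held 16, of which 9 were higher and 7 lower at 4 °C, and their share went from 4.14% to 5.40%. Most of this difference came from Traes_5DL_8BBB72707, listed at 0 at 23 °C; the other 15 genes took 4.14% at 23 °C and 4.47% at 4 °C.

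Summed FPKM as deposited was higher at 4 °C on 36 of the 41 chromosome arms, and after median-of-ratios scaling on 26, with 15 lower. The 5 arms with a lower deposited sum were 2AS (ratio of 4 °C to 23 °C 0.70), 2DS (0.73), 2BS (0.76), 4DS (0.95) and 5BS (0.99). The lower sums of group 2 rested on few genes in part. Without the 5 most abundant genes of each arm, the ratio was 0.97 for 2AS, 0.80 for 2BS and 1.18 for 2DS, and 2AS and 2BS were the only arms left below 1 in the deposited values; after scaling, 4 arms were. The highest ratio was on 5DL, at 1.43, and was 1.23 without its 5 most abundant genes. Reads of homoeologous genes can be assigned to each other's copies, so values of single arms within a homoeologous group are not fully separate measurements.

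**Figure D2:**
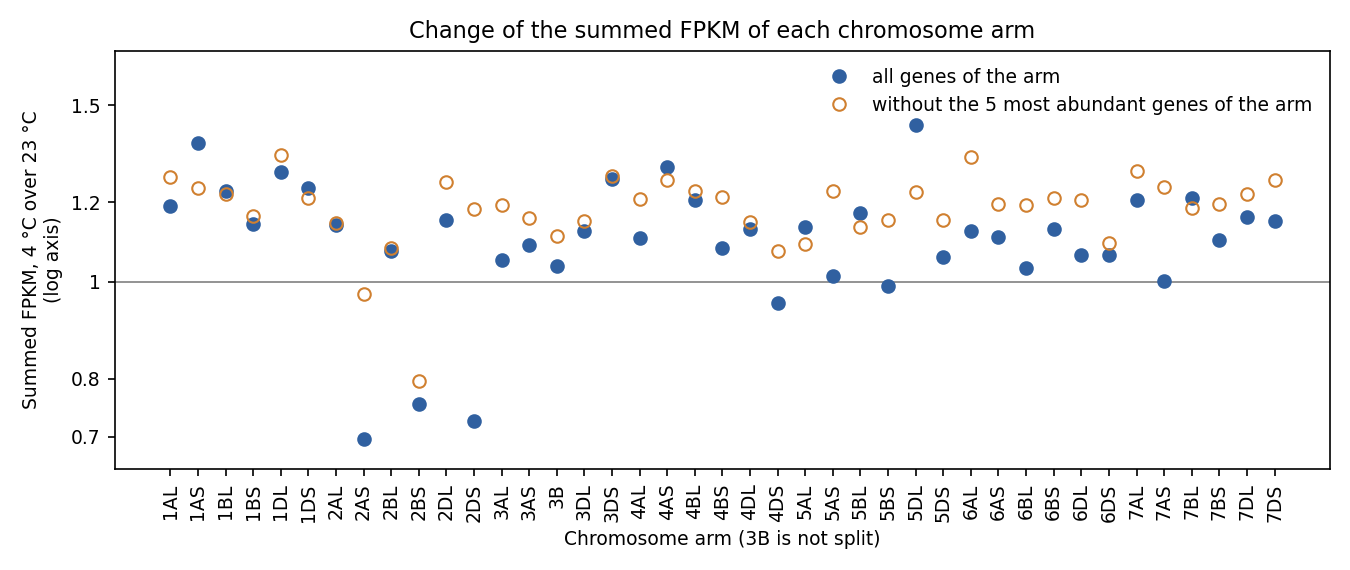
Each point is the ratio of summed FPKM at 4 °C to that at 23 °C for 1 chromosome arm, on a log axis, with all genes (filled) or without the 5 most abundant genes of the arm (open). The filled points of 2AS, 2BS and 2DS lie between 0.70 and 0.76, and the open point of 2DS lies at 1.18.

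Median log2 changes of the arms, in which genes that went up and down cancel, ranged from -0.04 on 6DS to 0.27 on 6AL. On 40 of the 41 arms, more genes were at least 2-fold higher at 4 °C than lower; on 6DS, 70 were higher and 85 lower. Against random lists of genes of like abundance, 7 arms lay outside the central 95%, where independent genes would give 2.05. Genes of an arm or of homoeologous arms need not be independent, so the number expected by chance is unknown. The arms 4AS (median 0.17), 4DL (0.16), 4BL (0.13) and 6AL lay above, and 1BS (-0.002), 6DL (0.05) and 6DS lay below. As background, 4AS is the counterpart of 4BL and 4DL, because an inversion exchanged the arms of 4A. Of the 6 settings compared, 6AL and 6DS were outside under 6, 1BS, 4AS, 4DL and 6DL under 5, and 4BL under 3. Random lists were matched on FPKM, but values on 6A were low and those on 6D high in both conditions (below). Genes of 6D were thus set against more abundant genes, and those of 6A against less abundant ones. The central 95% was 0.08 to 0.17 for 6DL and -0.04 to 0.14 for 6AL. The medians of 6BS (0.03) and 7BS (0.04) were lower than that of 6DL but within their own ranges. The median of 6DS, in contrast, was below the central 95% of every arm outside 6A, for example 0.03 to 0.15 for 4DS. This argues against the matching as the only reason for 6DS. How far the matching on FPKM placed 6AL, 6DL and 6DS outside was not tested.

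Genes of chromosome 6A had low values in both conditions, and the upper percentiles of 6D were high. Of 4038 gene IDs on 6A, 12.5% reached a mean of 1 FPKM, against 41.5% to 50.5% on the other A chromosomes, and 44.4% were listed at 0 in both conditions, against 21.5% to 30.7%. The 90th percentile of FPKM over 6A genes was 1.40 at 23 °C and 1.60 at 4 °C. On the other 6 A chromosomes it was 9.81 to 13.7 at 23 °C and 12.3 to 15.8 at 4 °C. On 6D it was 21.6 at 23 °C and 24.3 at 4 °C, above the 11.0 to 12.4 and the 12.4 to 14.8 of the other 6 D chromosomes. The share of 6D gene IDs that reached a mean of 1 FPKM was 50.04%, just above the 42.3% to 49.9% of the other D chromosomes, and 24.97% were listed at 0 in both conditions, within their 22.8% to 28.7%. On 6B it was 9.82 at 23 °C and 11.8 at 4 °C, within the ranges of the other B chromosomes (9.22 to 11.4 and 11.1 to 13.0). Relative to the median of the other chromosomes of the same subgenome, and over the mean of both conditions, the level was 0.12 for 6A, 0.95 for 6B and 1.8 for 6D. The number of genes with a mean of at least 100 FPKM was 10 on 6A, 32 on 6B and 107 on 6D.

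**Figure D3:**
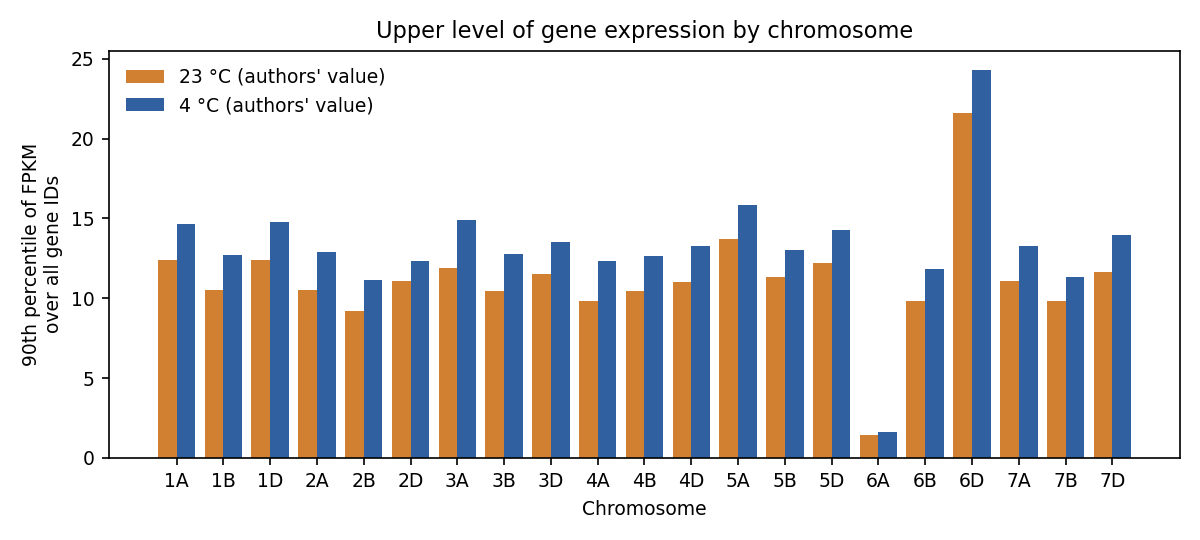
Bars show the 90th percentile of FPKM over all gene IDs of each of the 21 chromosomes, at 23 °C (orange) and 4 °C (blue), from the authors' single value per condition. The bars of 6A (1.40 and 1.60) lie below and those of 6D (21.6 and 24.3) above all others in both conditions.

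The D subgenome took a larger share of FPKM than A or B, and its share was higher in the cold. Genes of A chromosomes took 25.5% of all FPKM at 23 °C and 25.8% at 4 °C, those of B chromosomes 26.3% and 26.7%, and those of D chromosomes 29.6% and 31.5%. Without homoeologous group 6, with its low values on 6A and high values on 6D, the shares at 23 °C were 27.1% for A, 26.3% for B and 26.2% for D, so that D no longer had the largest share. At 4 °C they were 27.5%, 26.8% and 28.2%. The D share was higher at 4 °C by 1.92 percentage points, and by 1.28 without the gene Traes_5DL_8BBB72707. It was higher by 0.96 without the 100 most abundant transcripts, and by 2.05 without homoeologous group 6. Among transcripts with a gene ID alone, the share at 4 °C minus that at 23 °C was -0.60 percentage points for A and -0.49 for B, so that of the 3 subgenomes only D kept its direction. With 1 value per condition these differences have no error.

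Transcripts with no gene ID took 18.7% of all FPKM at 23 °C and 16.0% at 4 °C. The most abundant transcript of the table at 23 °C was one of them, with 18762 FPKM at 23 °C and 2614 FPKM at 4 °C, a ratio of 7.18. The next in this class had 6277 and 5379 FPKM at 23 °C and 721 and 1111 FPKM at 4 °C. These 3 transcripts made up 3.02% of all FPKM at 23 °C and 0.42% at 4 °C. Without them the class took 16.2% of the remaining FPKM at 23 °C and 15.6% at 4 °C. The 3 transcripts were picked as the highest of the class at 23 °C, a choice that favours lower values at 4 °C. Of 17972 transcripts in this class with a mean of at least 1 FPKM, 2050 were at least 2-fold higher at 4 °C and 2895 at least 2-fold lower, which is 11.4% and 16.1%. At 4-fold, 639 were higher and 606 lower. Of 59442 such transcripts with a gene ID, 15.0% were higher and 8.38% lower.

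The most abundant transcript of a gene was another one at 4 °C in 1667 of 13578 genes with several transcripts and at least 5 FPKM in both conditions, or 12.3%. In genes where the leading transcript took at least 60% of the gene's FPKM in each condition, it was another one in 52 of 7927, or 0.66%. Transcript values within a gene are estimates that divide shared reads, and their error is not in the table.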

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

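No paired analysis was possible because the table gives 1 value per condition and none per library; for the same reason no library could be left out and no variance setting tried, and depth is unknown. Levels were not tested, so a share or ratio below counts as moved whenever its printed value differs. The counts of higher (5318) and lower (2846) genes stayed within 1.5 times under no filter, median-of-ratios scaling, quantile normalization and without homoeologous group 6. They moved further with a pseudocount of 0.1 (4451 lower), a mean of at least 5 FPKM (3480 higher and 1533 lower, since fewer genes are tested) and transcripts in place of genes (8892 and 4983); in each of these settings higher genes outnumbered lower ones. The number of arms outside random lists was 5 to 10 over the planned settings. With median-of-ratios scaling of the arm sums, chosen after seeing the data, arms with a higher sum at 4 °C went from 36 to 26 and those with a lower sum from 5 to 15, or from 2 to 4 without the 5 most abundant genes of each arm. In the order A, B, D and no gene ID, the share at 4 °C minus that at 23 °C was 0.35, 0.47, 1.92 and -2.73 percentage points over all features, 0.24, 0.37, 1.88 and -2.49 at a mean of at least 1 FPKM, and 0.63, 0.43, 0.963 and -2.02 without the 100 most abundant features. Among alternatives chosen after seeing the data, it was 0.39, 0.52, 2.05 and -2.96 without homoeologous group 6, and 0.59, 0.72, 1.28 and -2.59 without the most abundant gene listed at 0 at 23 °C. With gene IDs alone, A (-0.60) and B (-0.49) reversed and D was 1.10; the class left out took 18.7% of FPKM at 23 °C and 16.0% at 4 °C, so the 4 °C denominator is reduced by less. The count of genes with another leading transcript was 52 in place of 1667 with a leading share of at least 60% in each condition. That rule leaves out genes whose transcripts were near a tie, so a lower count follows at least in part from the rule. The relative level of 6A was 0.0508 at the 75th percentile, 0.122 at 23 °C alone, 0.115 at 4 °C alone and 0.0846 over genes with 1 transcript. That of 6B was 0.960, 0.939, 0.935 and 1.02, and that of 6D 1.755, 1.86, 1.77 and 1.48.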

Other observations

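All tests in this part were chosen after the result was seen. Of the 32 genes that were under 1 FPKM at 23 °C and at least 100 FPKM at 4 °C, 16 lay on the 3 arms that held the most. In 10000 random draws of 32 from the 1223 genes with at least 100 FPKM at 4 °C, each counted on its own 3 fullest arms, the median was 9 and the highest 16, and 3 draws reached 16. Placement in proportion to genes at 100 FPKM or more thus seldom gave this count when genes were drawn as independent. It is not excluded by the rule used, which asked for a count above all draws. Copies of 1 locus on the same or homoeologous arms are not independent, so the draws may overstate how rare the count is. The fullest arms were 7DS with 7 genes, 7AS with 5, and 5BL and 5DL with 4 each. On 7AS, 7DS and 4AL, arms picked after the counts were seen, lay 15 of the genes. Only 3 of these were on 4AL, fewer than on 5BL or 5DL, so the draws above do not test this choice of arms. As background, the end of 4AL carries a segment that came from 7BS; the IDs give the arm alone, so whether the genes on 4AL lie in it is not known here. The 15 genes ranged from 100.4 to 547.1 FPKM at 4 °C, a ratio of 5.45. This does not decide whether reads of 1 locus were shared evenly among near-identical copies, since genes of several loci would differ in level with or without sharing, and the IDs do not say which genes are copies. A candidate explanation is a cluster of related genes that is on in the cold or in older leaves. Temperature, growth chamber and labelled weeks cannot be separated, and gene names, which would test it, were not used here.

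Low values on 6A and high values on 6D were present in both columns. The level of 6B, 0.946 of the other B chromosomes, argues against reads of 6A being assigned to 6B and 6D alike. The level of 6D, 1.8 times that of the other D chromosomes, is consistent with absence of 6A and extra copies of 6D in the sampled plants, as in the nullisomic-tetrasomic stocks known in wheat. This is a hypothesis, since the labels name no such stock, and over genes with 1 transcript the level of 6D was lower, at 1.48. Assignment of 6A reads to 6D alone, for example from a diverged or exchanged 6A or from the reference, cannot be told apart from it, because the relative levels of 6A and 6D add up to 1.92 and both explanations give a sum near that value. Of the 6A genes, 190 had a mean of at least 5 FPKM and 10 of at least 100 FPKM. Absence of 6A would need these values to come from reads of other chromosomes, which was not tested. Reads or DNA markers of 6A would be needed to decide.

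Genes with at least 10 FPKM in one condition were in part listed at exactly 0 in the other. Of 12533 genes with at least 10 FPKM at 4 °C, 41 were listed at 0 at 23 °C, 30 were above 0 and under 0.1 FPKM, a ratio of 1.37 (95% interval 0.86 to 2.18), and 180 were from 0.1 to under 1 FPKM. This does not decide whether failed estimates listed as 0 are among them. Of 10862 genes with at least 10 FPKM at 23 °C, 25 were listed at 0 at 4 °C, 2 were above 0 and under 0.1 FPKM, a ratio of 12.5 (95% interval 3.28 to 47.7), and 56 were from 0.1 to under 1 FPKM. Both intervals are Wilson intervals that treat genes as independent draws and hold no spread between libraries. An excess at exactly 0 is what failed estimates listed as 0 would give. Some of the genes at 0 at 4 °C, such as Traes_7AL_9EFCAA261 and Traes_7BS_1A4F10567, may thus be of that kind. The 4 °C column listed 31300 of all genes at 0, against 29810 at 23 °C, and its depth is unknown. The ratio therefore does not tell failed estimates from a higher floor of that column. Short transcripts, for which 1 read is worth more than 0.1 FPKM, stay open as well, since lengths were not used here. Of the genes at 0, 78.0% (at 23 °C) and 100% (at 4 °C) had 1 transcript, against 21.1% in each full set. These shares do not bear on length. A gene's FPKM is a sum, so a gene with several transcripts is at 0 only if all of them are.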
